A study of Mus musculus with 10 samples.

How the data were processed

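Ribosome profiling (Ribo-seq) sequences the stretches of mRNA that ribosomes protect from nuclease (footprints), and matched input RNA gives the amount of each mRNA. The series holds 10 mouse libraries, 1 per condition and kind. An immortalized bone marrow-derived macrophage line (iBMDM) is labelled WT, sgWdr4-1 or sgWdr4-2, for 2 guide RNAs against Wdr4. Tumour-associated macrophages (TAM), sorted by the surface protein F4/80 from liver tumours grown from Hepa1-6 hepatoma cells, are labelled Wdr4^ff or Wdr4^cKO, the latter from mice with a myeloid deletion. Each of these 5 conditions has 1 input library of polyadenylated RNA and 1 footprint library.

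The authors deposited 2 tables of TPM (transcript abundance scaled for gene length and to a fixed library total), one for the 6 iBMDM libraries and one for the 4 TAM libraries. Reads were handled with fastp 0.18.0 and Bowtie2, per the submitters' processing notes. The genome build, the annotation, the quantifier and whether reads mapping to several genes were shared out are not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown and no counting interval is given. In every library the values sum to about 1000000, so a transcript class that takes more of a library lowers all others. Each table lists 21956 rows and 21934 symbols. For 20 symbols with 42 rows in all, the row with the highest mean TPM was kept. Of the symbols, 19772 matched the table of gene identifiers and 19910 the RefSeq table; no coordinates are given because the build used is not known.

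Values were computed on the log2(TPM + 1) scale, which understates changes of low genes. Genes entered when mean input TPM and mean footprint TPM over a table's libraries were each at least 5, which left 7536 genes in the iBMDM table and 7101 in the TAM table. Translation efficiency was log2(footprint TPM + 1) minus log2(input TPM + 1) per condition. With TPM and no counts, no count model with an interaction term was fitted as the main test. Changes were taken within a table only. The size rule counted genes at least 2-fold apart (1 on the log2 scale), for the iBMDM table in the same direction under both guides. In the iBMDM table limma 3.58.1 in R 4.3.3 also compared the 2 guide lines with the 1 WT line (empirical Bayes with an expression trend, Benjamini-Hochberg adjusted p under 0.05, two-sided). That fit has 1 residual degree of freedom, takes its spread from the difference between guides, and assumes that the lone WT line varies likewise. The labels do not say that libraries came from separate cultures. The TAM table has 1 library per genotype and kind, so its differences have no replicate check and no p-value.

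Before the data were examined, 38 gene lists were fixed. For the 23 lists with at least 4 measured genes in a table, the median log2 change was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list below the 2.5th or above the 97.5th percentile is said to stand apart, which describes these libraries. About 1.2 of 23 lists would do so by chance if genes varied independently. Members of a list can move together between single libraries, so more could stand apart by chance. Some lists also share genes, so lists are not independent of each other. Col1a1, Col1a2 and Col3a1 are in both the extracellular matrix and the fibroblast list, and Atf3 in both the stress response and the immediate-early list. For cKO translation efficiency, as labelled, 4 lists stood apart above and 12 below. The other lists are reported by their TPM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

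The genes named were chosen by a rule fixed at the same time. For translation efficiency it took, per table, the 8 highest and 8 lowest genes past the size rule, and for input and footprints the 5 highest and 5 lowest. The ranking used the smaller of the 2 guide changes, or the cKO change, among genes with mean TPM of at least 10 in input and footprints. Gene models, pseudogenes, histones and mitochondrially encoded genes were left out of the ranking. Added were Wdr4, Mettl1 and up to 4 members per list and direction past the size rule. Marker genes given by level, genes passing limma, near-identical copies of named genes and genes said to be chosen after their values were seen were named besides. Some genes that the rule takes are not reported here.

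The limma step was tested on simulated data for the 7536 iBMDM genes. The simulated noise was normal with 1 spread per expression bin. It leaves out differences in spread between genes of a bin, so recovery in the real data may be lower. In simulated input RNA it recovered 88 of 100 genes set 2-fold apart and 100 of 100 set 4-fold apart, with 8 of 7336 unchanged genes called. In simulated footprints it recovered 0 and 16, with 2 unchanged genes called, and in simulated translation efficiency 0 and 10, with 1 called. The size rule called 773 of 7336 unchanged genes in simulated translation efficiency. The list step was tested with 30 random genes of the cKO comparison shifted by 0.5, which came out at the 99.97th percentile.

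The alternatives were a pseudocount of 0.1, mean TPM of at least 1 or 20, libraries rescaled to the same median, TPM rescaled without mitochondrially encoded, ribosomal protein and histone genes, limma without a trend, an interaction term without the pairing by line, and each guide line left out. Values with the ff and cKO footprint libraries crossed were added after the data were seen.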

Results

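The data were 5 input RNA and 5 footprint libraries of mouse cells, given as TPM in 2 separately normalised tables. The question, from the series' title, was how Wdr4 acts on translation efficiency. Wdr4 is the partner of the methyltransferase Mettl1, which places 7-methylguanosine on tRNA. The iBMDM table held lines labelled WT, sgWdr4-1 (guide 1) and sgWdr4-2 (guide 2), and the TAM table held sorted cells labelled Wdr4^ff (ff) and Wdr4^cKO (cKO). There was 1 library per condition and kind throughout, and read depth was unknown.

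Wdr4 did not follow its labels in every library. Input Wdr4 was 44.6 TPM in the library labelled WT, 31.3 TPM (70.1% of WT) in that labelled guide 1 and 44.5 TPM (99.8%) in that labelled guide 2. Wdr4 footprints were higher in the targeted lines, at 13.3 TPM in WT, 24.3 TPM (1.82-fold) under guide 1 and 26.9 TPM (2.01-fold) under guide 2. In the TAM table Wdr4 input was 39.8 TPM in ff and 20.9 TPM (52.6%) in cKO, while its footprints were 8.51 and 17.7 TPM (2.08-fold). Mettl1 input lay between 53.4 and 60.5 TPM in all 5 input libraries. A small edit made by a guide RNA need not lower the RNA, and gene-level TPM does not resolve a deleted exon. Groups are therefore named by their labels, and every direction below is one between libraries labelled so.

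Genes that define macrophages were near 0 in all 10 libraries. Of 20 macrophage identity genes, 16 were under 1 TPM in every input library, and 18 were under 5 TPM in every library. Adgre1, which encodes the F4/80 protein used for the sort, and Aif1 were listed at 0 in all 10 libraries. The highest value of Csf1r, the receptor for macrophage colony-stimulating factor, was 0.291 TPM, and of Lyz2, a lysozyme, 4.85 TPM. Cd14 (13.8 to 19.8 TPM in input) and Lgals3 (503 to 669 TPM) were the 2 members at 5 TPM or more in every input. Ptprc, the pan-leukocyte gene CD45, reached 0.112 TPM. Ptprc and the marker genes given by level, here and for the other cell types, were chosen after their values were seen.

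Several genes of fibroblasts and stellate cells were high. Input Col1a1 lay between 425 and 595 TPM, Col1a2 between 589 and 712 TPM, and Acta2, smooth muscle actin, between 2397 and 3785 TPM. Of the 14 genes of the fibroblast list, 7 reached 5 TPM in every input, and the other 7 were under 1 TPM in every input. Of 22 listed hepatocyte and hepatoma genes 20 were under 5 TPM in every library, Apoa1 and Apoa2 being the 2 at or above 5 TPM in every input. Among the markers of other cell types, 14 of 16 T cell, 10 of 11 B and plasma cell, 10 of 10 NK cell, 13 of 13 neutrophil, 10 of 11 dendritic cell, 7 of 9 Kupffer cell, 7 of 9 monocyte, 10 of 13 endothelial and 7 of 9 erythroid and platelet genes were under 1 TPM in every input. Of the 10 chemokine and chemoattractant receptor genes 8 were under 1 TPM in every input, as were 8 of 12 MHC class II genes and 4 of 4 sex-linked genes. Replication-dependent histones, which lack poly(A) tails, took 0.010% to 0.013% of input TPM and 2.46% to 4.06% of footprint TPM.

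**Figure D1:**
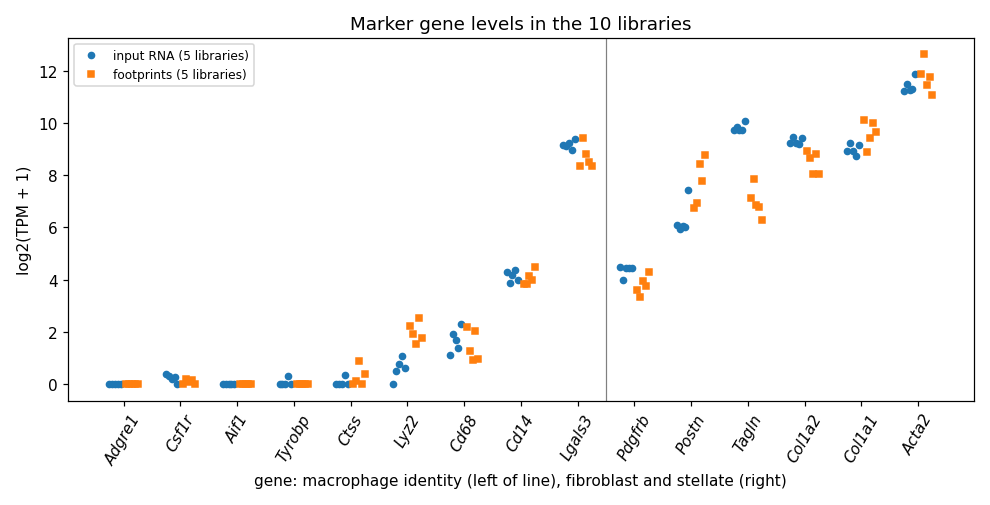
Levels of 15 marker genes, picked from the macrophage and fibroblast lists after their values were seen, on the log2(TPM + 1) axis; each point is 1 of 5 input (circles) or 5 footprint (squares) libraries. Adgre1 and Aif1 sit at 0 in all 10, while Col1a1 is at 425 TPM or above in every library.

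Input libraries of the 2 tables were close to each other. Over 5412 genes with a mean of at least 20 TPM, the robust SD of the log2 difference between the inputs labelled WT and ff was 0.115, against 0.278 between ff and cKO. It was 0.080 between WT and guide 2, 0.212 between WT and guide 1, and 0.172 between guide 1 and cKO. The tables were normalised separately, so these distances are descriptive.

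Input RNA differed little between the iBMDM lines. Past the size rule under both guides were 1 higher and 2 lower genes; the lower ones were Ece1, an endothelin-converting enzyme (log2 change -1.32 under guide 1 and -3.05 under guide 2), and Rabl2, a small GTPase (-1.08 and -1.15). Guide 1 alone had 24 higher and 6 lower genes and guide 2 alone 2 and 3. Under guide 1, medians stood apart and above 0 for glycolysis (0.34), stress response genes (0.33), extracellular matrix (0.28) and immediate-early genes (0.29), and below 0 for cytosolic ribosomal proteins (-0.24) and cholesterol synthesis (-0.23). The same medians under guide 2 lay between -0.03 and 0.01, none of them apart, and those of glycolysis and immediate-early genes turned negative with rescaling to the same median. Fibroblast and stellate markers, which share collagen genes with the extracellular matrix list, stood apart too under guide 1 (0.24) and were at 0.01 under guide 2. Limma did not call Ece1 or Rabl2, past 2-fold under both guides, so an uncalled gene is not shown to be unchanged. By limma 0 of 7536 genes passed in either direction, with 55 at an unadjusted p under 0.05 and a lowest adjusted p of 0.871.

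Translation efficiency in the iBMDM table passed the size rule under both guides for 68 higher and 154 lower genes. The higher ones included Ppcdc, of coenzyme A synthesis (2.90 under guide 1 and 2.67 under guide 2), Heatr1, of ribosome biogenesis (1.95 and 2.26), Mis12, of the kinetochore (2.34 and 1.91), Mid1ip1 (2.68 and 1.60) and the transcription factor Runx2 (1.70 and 1.54). Both Ppcdc values rest on the shared WT footprints, which were at 1.835 TPM. The other higher genes named rest on that WT library too, with footprints of 5.17 TPM for Mid1ip1, 5.92 TPM for Heatr1, 8.46 TPM for Runx2 and 14.55 TPM for Mis12. The lower ones included Nipa2, a magnesium transporter (-2.61 and -2.38), Socs6 (-2.84 and -2.28), Rusc2 (-2.43 and -2.23), Plau, the urokinase protease (-1.97 and -2.10), Fez1 (-1.93 and -2.21), Ifnar1, an interferon receptor chain (-1.95 and -1.81), Kansl3 (-1.85 and -1.78) and Alkbh1 (-2.04 and -1.74). Rps27rt (2.63 and 1.61) has a near-identical copy, Rps27, and is uncertain. Guide 1 alone had 1114 higher and 1030 lower genes and guide 2 alone 266 and 367, and 26 genes went opposite ways.

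The 68 and 154 genes were fewer than in simulated unchanged lines and more than independent lists would share. Simulated unchanged lines set against 1 shared WT line, with noise sized from the difference between guides and so widened by the guide 1 footprints, gave 387.3 higher and 387.8 lower genes under both guides. The overlap of independent lists would be 39.3 and 50.2. The guides' changes correlated across genes at r = 0.324 (covariance 0.18), where simulated unchanged lines gave r = 0.501 (covariance 0.425). The simulation gave every line the same noise, which by itself sets its r. The real changes had unequal robust SDs, 0.967 under guide 1 and 0.533 under guide 2. The simulated counts and r therefore cannot show whether the guides agree less or more than unchanged lines would. Genes are not independent replicates, and with 1 WT library the control could not be split, so part of any agreement may come from the shared WT line.

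By limma, 5 genes passed for translation efficiency, named here because they are few. Gm14305 (log2 change 5.23, SE 0.77, adjusted p = 4.4e-08), Rpl9-ps6 (4.08, SE 0.55, adjusted p = 1.6e-09) and Add3, a membrane skeleton protein (2.47, SE 0.59, adjusted p = 0.0487) rose under both guides. Lyrm9 (-3.68, SE 0.61, adjusted p = 3.9e-06) and Morn2 (-2.48, SE 0.58, adjusted p = 0.0322) fell under both. Rpl9-ps6 is a pseudogene of Rpl9 and shares its sequence, and Gm14305 was listed at 0 in the WT footprints. Lyrm9 input was 1.04 TPM in WT, 8.06 TPM under guide 1 and 6.43 TPM under guide 2. At an unadjusted p under 0.05 there were 165 genes. The 5 genes had input under 20 TPM in every iBMDM library, so a mean of at least 20 TPM left them out before the test. With the interaction term without pairing, which did test them, they were not called.

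Footprints in the iBMDM table passed the size rule for 56 higher and 108 lower genes. Among the higher were Ppcdc (2.52 and 2.86), Mis12 (2.10 and 1.81), Add3 (3.25 and 1.67) and Heatr1 (1.61 and 2.20), and among the lower Fez1 (-2.33 and -2.34), Nipa2 (-2.15 and -2.29), Socs6 (-2.67 and -1.88), R3hdm2 (-2.56 and -1.73) and Rusc2 (-1.69 and -2.33). By limma 1 gene rose, Gm14305 (5.02, adjusted p = 6.3e-05), and 65 were at an unadjusted p under 0.05. Guide 1 alone had 1210 higher and 776 lower genes and guide 2 alone 228 and 349. Under both guides, simulated unchanged lines gave 387.9 higher and 389.3 lower genes, and independent lists would share 36.6 and 35.9. The simulation again gave every line the same noise, so it cannot show how many of these genes unchanged lines would give.

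The guide 1 footprint library stood apart from the others. Mitochondrially encoded genes took 0.78% of its TPM, against 14.6% in WT, 10.3% under guide 2, 9.94% in ff and 13.6% in cKO. Its robust SD of log2 differences from the WT footprints was 0.934, against 0.479 for guide 2. Left without guide 1, the counts for translation efficiency are the 266 and 367 of guide 2 alone.

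Groups of genes that stood apart in the same direction under both guides and in cKO were few. Cytosolic ribosomal proteins had higher median translation efficiency, by 0.74 under guide 1, 0.50 under guide 2 and 0.52 in cKO over 76 genes. Random lists matched on expression were themselves at 0.315, 0.148 and 0.065. Some members, such as Rps27 and Rpl9, have near-identical copies, and how reads mapping to several genes were handled is unknown. Extracellular matrix genes were lower (-0.76, -0.75 and -1.05), with Col5a1 and Itga5 past the size rule in each comparison (Col5a1 -1.66, -2.18 and -2.63). Lysosome genes (-0.75, -0.29 and -0.59) and MHC class I genes (-0.86, -0.55 and -0.71) were also lower. Cholesterol synthesis genes were at 0.47 under guide 1, within the random range, and stood apart at 0.56 under guide 2 and 1.08 in cKO; Nsdhl, Mvd and Idi1 were past the size rule in each comparison. Mitochondrial ribosomal proteins were at 0.28, also within the range under guide 1, and at 0.22 and 0.13, both apart. No member of these 6 lists passed limma, over all genes or adjusted over the list alone. The cKO values rest on the labels of the ff and cKO footprint libraries. With those crossed, the cKO medians would be -0.001 for ribosomal proteins, 0.23 for extracellular matrix, -0.06 for lysosome, -0.30 for MHC class I, -0.11 for cholesterol synthesis and 0.13 for mitochondrial ribosomal proteins, of which MHC class I alone would stand apart.

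Other groups stood apart in some comparisons and not in others. Stress response genes were at -0.21 under guide 1, within the random range, and stood apart at -0.61 under guide 2. Phagocytic receptors stood apart at -0.81 under guide 1 and were at -0.16 under guide 2. Aminoacyl-tRNA synthetases stood apart at 1.22 under guide 1, were at -0.11 under guide 2, and stood apart at -0.74 in cKO. Glycolysis (0.99, -0.11 and -0.87) and mitotic genes (0.94, -0.18 and -0.63) went likewise, and DNA replication genes (1.00, 0.01 and -0.42) stood apart under guide 1 alone of the 3 comparisons; the differences were not tested. Translation factors were at 0.78 (apart), 0.15 and 0.06. The tRNA methyltransferase list was at 0.19, -0.02 and -0.04, the last 2 becoming 0.07 and 0.25 with rescaling to the same median, and the nuclear-encoded respiratory chain at 0.26, 0.10 and 0.03, none apart. Adjusted over the list alone, 12 of 13 mitochondrially encoded genes and, of 13 p53 targets, Pmaip1 (adjusted p = 0.0341) fell for translation efficiency by limma, and over all genes none did. The mitochondrially encoded median was -3.90 under guide 1, whose footprint library stood apart, and -0.44 under guide 2. With the ff and cKO footprints crossed, cKO medians would be 0.48 for aminoacyl-tRNA synthetases, 0.53 for mitotic genes, 0.41 for DNA replication, 0.28 for translation factors and 0.53 for tRNA methyltransferases, all apart, and 0.22 for glycolysis and 0.10 for the respiratory chain, neither apart.

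**Figure D2:**
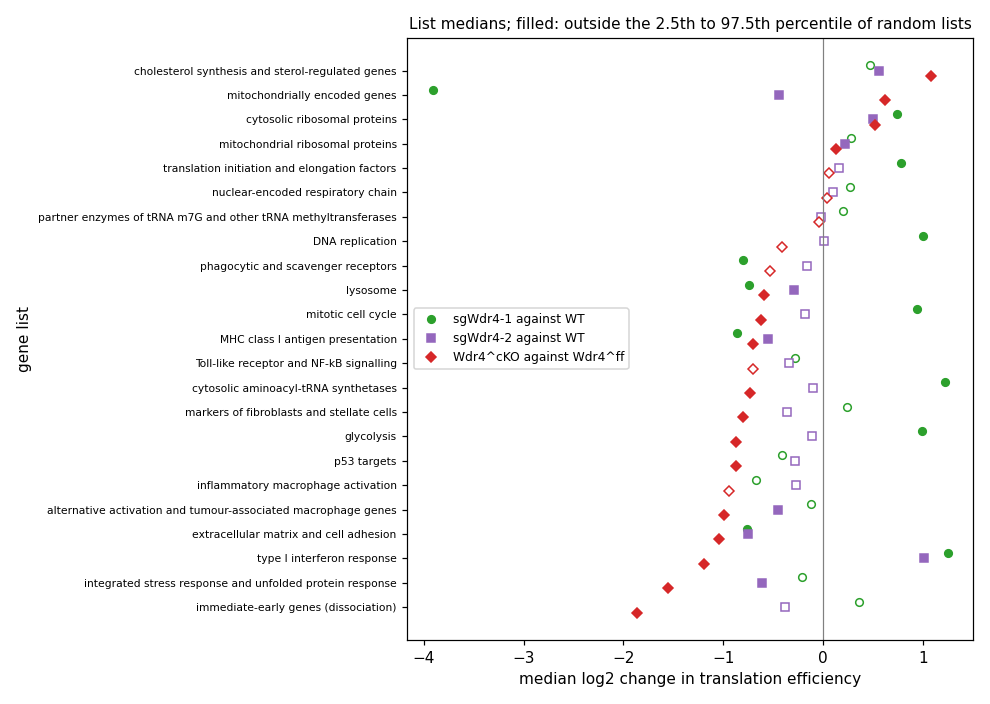
Median log2 change in translation efficiency of 23 gene lists, 1 per line, for guide 1 (circles), guide 2 (squares) and cKO (diamonds); filled symbols stood apart from random lists. Ribosomal proteins lie above 0 and extracellular matrix genes below 0 in all 3 comparisons under the labels as given.

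Between the libraries labelled cKO and ff, 101 genes were at least 2-fold higher in input RNA and 12 lower. The highest were Vldlr (3.42), Trib3, a pseudokinase of the integrated stress response (2.36), Cdkn1a, the p53 target p21 (2.09), Has2, a hyaluronan synthase (1.96), and Bst2, an interferon-induced protein (1.91). Vldlr input in ff was low, at 1.829 TPM. The lowest were Pnrc2, of mRNA decay (-2.11), Rabl2 (-1.92), Zfp950 (-1.58), Ece1 (-1.25) and Msln, mesothelin (-1.17). Stress response genes stood apart with a median of 0.62 (6 of 23 past 2-fold), as did inflammatory genes (0.84, including Ptgs2 at 1.36), immediate-early genes (0.60), extracellular matrix (0.47) and glycolysis (0.37). The inflammatory median rests on 6 measured genes, and 17 of 24 inflammatory genes were under 1 TPM in every input. Fibroblast and stellate markers, which share collagen genes with the extracellular matrix list, stood apart too, with a median of 0.40 (5 of 6 higher, Postn at 1.42). Cholesterol synthesis (-0.53), ribosomal proteins (-0.25) and tRNA methyltransferases (-0.26) stood apart below.

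Translation efficiency was at least 2-fold higher in cKO for 286 genes and lower for 1135. Higher were Dus2, a tRNA dihydrouridine synthase (4.09; footprints 4.07 TPM in ff and 100.2 TPM in cKO), Ctxn1 (3.14), Serf1 (2.35), Prrx2 (2.30), Nsdhl (2.25) and Ipmk (2.16). Lower were Vldlr (-5.32), Cdkn1a (-4.77), Trib3 (-4.14), Nppb, a natriuretic peptide (-3.98) and F3, tissue factor (-3.76). The Vldlr value rests in part on an ff input of 1.829 TPM. Kpna2rt (2.75), Sap18b (-7.45) and Rnaset2b (-6.87) have near-identical copies and are uncertain. The median gene lay at -0.25, and with libraries rescaled to the same median, which centres the changes by construction, the counts were 596 higher and 641 lower. With TPM rescaled without mitochondrially encoded, ribosomal protein and histone genes they were 477 and 1014, and with the ff and cKO footprint libraries crossed they would be 393 and 290.

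Stress response genes had the median -1.56 for translation efficiency in cKO (16 of 23 at least 2-fold lower) and immediate-early genes -1.86 (10 of 11). Extracellular matrix genes were at -1.05 (11 of 21 at least 2-fold lower), p53 targets at -0.87 and alternative activation genes at -0.99, all apart. Fibroblast markers were at -0.80 and also stood apart. Inflammatory genes (-0.94), NF-kB signalling (-0.71) and phagocytic receptors (-0.54) did not. The alternative activation median rests on 9 measured genes, with 16 of 29 listed genes under 1 TPM in every input. The inflammatory median rests on 6, with 17 of 24 under 1 TPM. Of cholesterol synthesis genes, 12 of 21 were at least 2-fold higher. These values rest on the labels of the ff and cKO footprints. With those crossed the medians would be 0.05 for stress response, 0.33 for immediate-early, 0.23 for extracellular matrix, 0.19 for p53 targets, 0.01 for alternative activation, -0.006 for fibroblast markers and -0.11 for cholesterol synthesis, none apart.

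Footprints in cKO were at least 2-fold higher for 194 genes and lower for 579; after rescaling to the same median these were 359 and 327, and without those gene classes 306 and 548. With the footprint libraries crossed, each footprint change would turn its sign, with 579 higher and 194 lower. Dus2 (4.32), Ctxn1 (2.97), Add3 (2.58) and Zdhhc3 (2.16) were among the highest, and Nppb (-2.94), Atp8b2 (-2.71) and Cdkn1a (-2.68) among the lowest. Input and footprints moved apart. Of the 101 genes higher in cKO input, 84 were lower in cKO footprints, 38 of them by 2-fold or more, while 63.9% of all genes were lower. Across genes past 2-fold in input the slope of footprint on input change was -0.38 (95% bootstrap interval over genes -0.61 to -0.19, 113 genes). Cdkn1a input was 7.62 TPM in ff and 35.7 TPM in cKO, and its footprints 58.9 and 8.36 TPM.

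**Figure D3:**
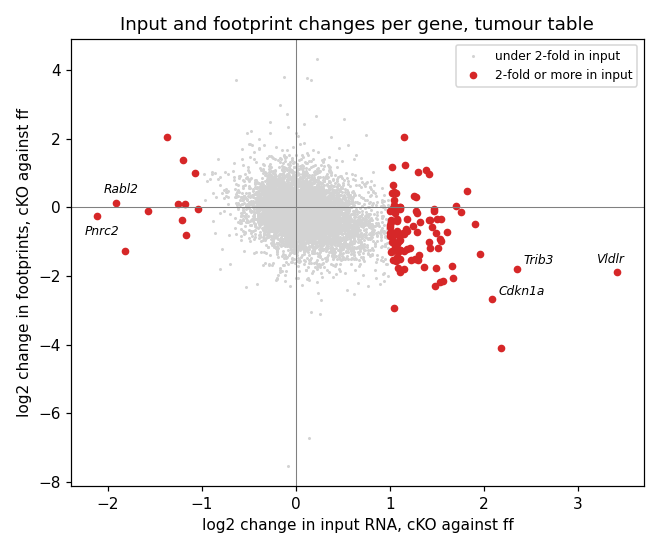
Log2 change in footprints (vertical) against log2 change in input RNA (horizontal), cKO against ff, for each of 7101 genes (points); red marks genes 2-fold or more apart in input. Of the 101 genes at the right, 84 lie below 0.

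Across 6927 genes measured in both tables, the mean translation efficiency change of the guides correlated with that of cKO at r = 0.215. Guide 1 alone gave r = -0.02 and guide 2 alone 0.495. For footprints the values were 0.020, -0.26 and 0.439, and for input 0.494, 0.625 and 0.003, so that cKO lay with guide 1 in input and with guide 2 in footprints. All values for translation efficiency rest on the labels of the footprint libraries. Past the size rules for translation efficiency, 17 genes were higher in both tables, where 2.45 would be shared by independent lists, and 76 were lower, against 21.03. Guide 1 alone shared 31 higher genes with cKO, against 38.0, and 208 lower, against 152.1, with 206 opposite. Guide 2 alone shared 74 higher genes, against 9.81, and 172 lower, against 47.8, with 20 opposite. With the ff and cKO footprints crossed, both guides would share 8 higher genes with cKO, against 3.29, and 5 lower, against 5.18, with 21 opposite. The 17 included Mvd, Nsdhl and Idi1 of cholesterol synthesis. The tables share no library, and 8 genes past both size rules went opposite ways under the labels as given.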

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

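Of the tests weighed here, that of summed copies was set before its result was seen; those on cell identity and on input against footprints were chosen after, and the reading of the slope for buffering was revised after its result, that of crossed libraries replaced a first version that only restated the pattern, and that of copies was narrowed after its result was seen, its pairs having been picked from the members' values.

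Flagged results were past the size rule, or for lists stood apart, in one direction under both guides and in the other in cKO. They were sought among the gene lists, the genes taken by the naming rule, those passing limma and the near-identical copies. The differences between the tables were not tested. Over all genes, 10 were past the size rules in opposite directions in footprints and 8 in translation efficiency. Mitochondrially encoded genes had footprint medians of -4.13, -0.54 and 0.40, and translation efficiency medians of -3.90, -0.44 and 0.61. The type I interferon list, with 4 measured genes in each table that need not be the same, had translation efficiency medians of 1.25, 1.01 and -1.19. In cKO 1 of the 4 was higher and 3 were lower. Ifit2 did not reverse in footprints: its translation efficiency was higher under both guides (1.16 and 1.44) and its footprints were higher in cKO (1.11). With a mean of at least 1 TPM the guide 2 median became -0.256. Hspa1b, a heat shock protein, had footprint changes of 3.21, 1.33 and -1.37 and translation efficiency changes of 3.56, 1.25 and -1.86. Kpna2, an importin with a near-identical copy, had footprint changes of 2.42, 1.33 and -2.33 and translation efficiency changes of 2.497, 1.395 and -1.791. Nipa2 footprints were at -2.15, -2.29 and 1.10. Lyrm9 translation efficiency was at -5.11, -2.25 and 2.28. With the ff and cKO footprints crossed, the cKO footprint values would turn their sign, and the translation efficiency medians would be -0.24 for mitochondrially encoded and -1.34 for type I interferon genes.

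Macrophage genes were near 0 and mesenchymal genes high in every library, although the labels name macrophages and an F4/80 sort, which would remove other cells. In every input 10184 genes were at 1 TPM or more, but TPM keeps no depth, so shallow sequencing could not be tested. Macrophages as the main cell type with mesenchymal cells mixed in are argued against by the highest input value of the identity genes other than Cd14 and Lgals3, 3.93 TPM, beside at least 425 TPM of Col1a1. Loss of macrophage identity after targeting of Wdr4 is argued against by the libraries labelled WT and ff, where those genes reached 4.85 TPM at most. A candidate explanation that stays open is that the columns hold libraries of another kind of cell than their labels name: the WT and ff inputs, from a cell line and from sorted tumour cells by label, differed by a robust SD of 0.115, less than the 0.278 between ff and cKO.

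Genes higher in cKO input were lower in cKO footprints. The WT footprints lay nearer ff, by 0.207 in robust SD over 7453 genes, as did the WT input, which speaks against crossed footprint libraries of the 2 genotypes. For guides 1 and 2 the footprints lay nearer the genotype that the input did not, as they also would with the footprints of the guides exchanged. These 2 lines cannot decide it. Guide 2 footprints lay nearer cKO (0.456, against 0.536 from ff), which correct labels could also give for a targeted line. Guide 1 footprints lay far from both (0.993 from ff and 1.197 from cKO). Crossed libraries therefore cannot be told apart from correct ones. Buffering, in which footprints stay level, stays open with that: the slope's interval over genes lay below 0 (upper bound -0.186), but its sign turns if the libraries were crossed. Lower translation of induced RNAs in the libraries labelled as targeted stays open too, as guide 1 gave a slope of -0.003 (95% interval -0.34 to 0.29, 30 genes).

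Large footprint changes were seen for genes with a near-identical copy. Rnaset2b went from 108 to 0.022 TPM in cKO while Rnaset2a went from 55.2 to 107 TPM, and Kpna2rt from 11.4 to 68.3 TPM while Kpna2 went from 80.0 to 15.2 TPM. Reads divided differently between copies could give this, and cannot be told apart from real changes with these pairs. Of 9 comparisons with a member past 2-fold, the sum of both copies stayed within 2-fold in 6 and moved past it in 3, all 3 under guide 1 (Kpna2rt 1.70, Rpl9-ps6 1.32, Rnaset2b -1.19). A division of reads alone does not give a moved sum, but these 3 do not argue against one. Under guide 1, 1210 higher and 776 lower of 7536 genes passed 2-fold in footprints. The Rpl9-ps6 sum was mostly Rpl9 (1019 TPM in WT and 2485 TPM under guide 1). Rnaset2b and Rnaset2a were both listed at 27.417 TPM under guide 1. In 3 of the 9 the member's change alone would have moved the sum past 2-fold, and there the sum stayed within it in 2, with a median absolute log2 change of 0.605.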

How the results depend on the processing

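The tests of agreement between the tables without either guide line, and of agreement between guides and between tables without mitochondrially encoded, ribosomal protein and histone genes, and all values with the ff and cKO footprints crossed, were chosen after the data were seen, as was the line of 0.1 past which a correlation is given here; the other alternatives were planned. Counts are higher and lower genes. Those within 1.5-fold of the main count may be left out, so the loss of a single call may not show. Filters of 1 and 20 TPM test more and fewer genes (9923 and 4008 iBMDM, 9795 and 3590 TAM), and a left-out guide line leaves 1 line to pass; for every other move the cause was not tested. Depth is unknown, so what depth limits cannot be given. The translation efficiency test pairs input and footprints by line; conditions cannot be paired with each other, with 1 library of a kind in each, and limma without a guide line has no residual degrees of freedom.

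By the size rule, a mean of at least 1 TPM gave 7 higher genes for iBMDM input, 132 and 211 for iBMDM footprints, 144 and 313 for iBMDM translation efficiency, 204 and 22 for TAM input, 325 and 983 for TAM footprints and 1853 lower for TAM translation efficiency. At 20 TPM these were 0, 17 and 26, 25 and 44, 35 and 6, 60 and 170, and 125 and 399. Rescaling to the same median gave 359 and 327 for TAM footprints and 596 and 641 for TAM translation efficiency. TPM without mitochondrially encoded, ribosomal protein and histone genes gave 2 higher for iBMDM input, 175 lower for iBMDM footprints, and 306 and 477 higher for TAM footprints and TAM translation efficiency. Leaving out a guide line gave, for iBMDM, input 2 to 24 higher and 3 to 6 lower, footprints 228 to 1210 and 349 to 776, and translation efficiency 266 to 1114 and 367 to 1030.

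By limma, input calls were 1 higher at 1 TPM, 1 higher and 3 lower when rescaled to the same median, and 1 higher without those gene classes. Footprint calls were 4 higher and 1 lower with a pseudocount of 0.1, 2 and 2 at 1 TPM, 0 higher at 20 TPM, and 1 lower with median rescaling, without those gene classes, or without a trend. Translation efficiency calls were 6 lower at 1 TPM, 0 and 0 at 20 TPM, 1 lower with median rescaling and without those gene classes, and 0 and 0 with the interaction term without the pairing by line, against 3 and 2 with it.

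The correlation of the mean guide change with cKO became 0.003 without sgWdr4-1 and 0.625 without sgWdr4-2 for input, 0.439 and -0.257 for footprints, and 0.495 and -0.024 for translation efficiency. Rescaling to the same median shifts all genes of a comparison nearly alike, so it does not test the percentiles of lists; it changed the sign of 23 of 276 medians, none of which stood apart. List medians were not recomputed without those gene classes. Of 801 with a pseudocount of 0.1 or a mean of at least 1 or 20 TPM, 762 kept their side of the random range, 18 newly stood apart, 18 no longer did, and 3 no longer did and turned their sign. Of these 801, 23 changed sign, the 3 among them being of the type I interferon list at a mean of at least 1 TPM: guide 2 footprints (-0.264) and translation efficiency (-0.256), and mean input (0.007). Of 1175 named gene values, 1110 kept their side of the size rule and 65 crossed it, and none past the rule changed sign. The filters of 1 and 20 TPM leave the change of a gene as it was, so their 260 and 143 values could not move. Of the 65, 42 came with rescaling to the same median (218 kept), 21 without those gene classes (231 kept) and 2 with a pseudocount of 0.1 (258 kept).

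With the footprint libraries of ff and cKO crossed, counts for cKO would be 579 and 194 in footprints and 393 and 290 in translation efficiency. Crossing turns the sign of each footprint change by construction. Translation efficiency medians in cKO that stood apart would turn to -0.001 for ribosomal proteins, 0.482 for aminoacyl-tRNA synthetases, 0.047 for stress response, 0.013 for alternative activation, 0.534 for mitotic genes, -0.243 for mitochondrially encoded genes (footprints -0.401), 0.221 for glycolysis, -0.111 for cholesterol synthesis, 0.228 for extracellular matrix, 0.188 for p53 targets and 0.329 for immediate-early genes.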

Other observations

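The test of exchanged guide footprints was chosen after the pattern was seen, and its reading was revised after its result.

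Ribosomal protein transcripts differed widely in footprint level. In ff, Rps7 had 1444 TPM in input and 5.01 TPM in footprints, and Rpl22l1 149 TPM and a listed 0, while Rps12 had 4224 and 1841 TPM. In cKO these footprints were 15.7, 12.9 and 5204 TPM. How reads mapping to several genes were handled is unknown, so a low listed value need not mean few ribosomes. Mt1, a metallothionein chosen after its values were seen, had 713 TPM in WT input and 17088 TPM in WT footprints, and 678 and 19044 TPM in ff, against footprints of 9437 TPM under guide 1, 7971 TPM under guide 2 and 8062 TPM in cKO.

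Ccn2, a secreted matrix protein also chosen afterwards, had 3402 TPM in WT footprints, 4858 TPM under guide 1, 1096 TPM under guide 2, 5007 TPM in ff and 1530 TPM in cKO. Its input was 977, 1919, 999, 1010 and 3206 TPM in the same order.

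By correlation across genes, cKO lay with guide 1 in input and with guide 2 in footprints. A candidate explanation is that the footprint libraries of guides 1 and 2 were exchanged, which would alter every per-guide translation efficiency value. Over 29 genes at least 2-fold apart between the guide inputs, the slope of the footprint difference on the input difference was 0.578 (95% bootstrap interval over genes 0.154 to 1.10), with 25 in the same direction. That would argue against an exchange if footprints followed RNA, but in cKO, as labelled, they ran opposite (slope -0.38), and with such a reversal an exchange would give a positive slope too. An exchange therefore cannot be told apart from correct labels.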
